A study of Mus musculus with 15 samples.

How the data were processed

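RNA from 15 primary mouse mammary tumours was measured on Affymetrix Mouse Gene 2.0 ST arrays, 1 array per tumour. The deposited table held 41345 probe sets by 15 arrays with 0 missing values. Its values were taken as log2 expression per probe set as the authors deposited them; the labels state no scale, and the log2 scale was read from the range of the values. The submitters' processing notes name RMA, which corrects background and normalises and summarises probes, and Partek, with versions not given in the sources used here. The deposited values entered the tests without further scaling. They come without detection calls, so no gene could be set against a measured background. For arrays no read depth exists, and their number limits the precision: the median standard error of a difference between groups was 0.173, 0.16, 0.16 and 0.154 for the 4 comparisons in the order of the report.

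Gene names came from the annotation table supplied with the series. Of the 41345 probe sets, 23521 carried 1 gene symbol, 1820 several and 16004 none, and the latter are unnamed here. Only probe sets with 1 symbol were tested as genes. Where a gene had several (1082 genes), the probe set with the highest mean over all arrays stood for it, which left 22180 genes. Entrez identifiers of 23328 of the 23521 probe sets matched the RefSeq table for assembly GRCm38.p6, used for names alone, with 0 renamed. No coordinates are given, because the genome build of the array annotation is not stated. Kras, Krt5, Stat1, Cd74, Ldlr and Hmgcr were among the list genes left untested because no probe set carried their symbol alone.

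Groups followed the genotype and pathology in the labels: 3 Neu tumours, 4 KRas tumours, 4 R26KRas adenocarcinomas and 4 R26KRas poorly differentiated carcinomas. The labels call the tumours independent, but the source names of 3 R26KRas tumours share an animal code, and these were kept as separate replicates. Labels give neither batches nor scan dates. The RNA numbers in the titles run in group order, so an effect of handling order cannot be separated from group. A linear model with 4 group means was fitted to all 15 arrays with limma 3.58.1 (statmod 1.5.0) in R 4.3.3, with eBayes moderation and two-sided tests. Adjusted p values are by Benjamini-Hochberg over the 22180 genes of a comparison, and a gene passed at an adjusted p below 0.05. The 4 comparisons were KRas minus Neu tumours, R26KRas adenocarcinomas minus KRas tumours, R26KRas poorly differentiated carcinomas minus adenocarcinomas, and the mean of the 2 R26KRas groups minus Neu tumours. Genes with groups that did not overlap were counted beside the share expected by chance.

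For genes in groups, 27 lists (milk, luminal, basal, squamous, tight junction, mesenchymal, stromal, immune, metabolic and signalling genes, cell cycle, other tissues and the drivers) were fixed before the data were examined. Lists were tested with camera, which compares a list with all other genes, at an inter-gene correlation of 0.01. Alternatives were camera with the correlation estimated from the data and fry, all adjusted by Benjamini-Hochberg over the 27 lists of a comparison. A list score per tumour is the mean over the list's genes of the deviation from the gene's mean over all tumours. Genes named in the report were Erbb2, Kras and Pik3ca, the 5 largest rises and 5 largest falls among genes that passed without overlap of the groups, and up to 18 genes from the lists in order of camera p (3 per list that passed, 2 per other list). Predicted genes, small RNAs and large receptor families were left out of the largest changes. Members named as examples of a list were chosen after the values were seen.

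Alternatives covered quantile normalization, centring on array medians, 2 filters on dim genes (above the median or above the lower quartile of probe set means), the mean of a gene's probe sets, eBayes with trend and robust options, fits of the compared groups alone, array weights, and a minimum 2-fold difference. The animal was also fitted as a random block, averaged within its group, or removed, and each tumour was left out in turn. The removal of that animal's 3 tumours was added after the values had been seen. The gene test was tested on simulated data with 10 sets and 200 changed genes each. At 2-fold it found 66.9% of changed genes for KRas minus Neu and 69.9% for R26KRas adenocarcinomas minus KRas. For poorly differentiated minus adenocarcinomas it found 73.4% and for R26KRas minus Neu 79.6%. Of its calls 4.29% to 5.72% were false. The simulated noise was independent, with 1 SD per gene for all groups and no shared animal, so these shares hold only under those settings. In the data KRas tumours varied more, with a median SD per gene of 0.247 against 0.179 to 0.187 in the other groups.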

Results

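Gene expression was measured in 15 primary mammary tumours from mice of 3 genotypes, with 1 Affymetrix Mouse Gene 2.0 ST array per tumour. In MMTV-Neu mice a mouse mammary tumour virus promoter drives the Neu oncogene, a form of Erbb2. KRas(G12D/+);CreT mice carry 1 activated Kras allele, and the remaining genotype adds R26(H1047R/+) to it. The labels name no gene for R26(H1047R/+), which is taken here as the activated H1047R form of Pik3ca, the catalytic subunit of PI3-kinase, placed at the Rosa26 locus, and they do not expand CreT. The 3 MMTV-Neu tumours were solid nodular carcinomas (Neu tumours) and the 4 KRas(G12D/+);CreT tumours complex adenocarcinomas (KRas tumours). The other 8 tumours comprised 4 complex adenocarcinomas (R26KRas adenocarcinomas) and 4 poorly differentiated carcinomas (R26KRas poorly differentiated carcinomas). By the codes in their source names, R26KRas adenocarcinomas 1 and 4 and R26KRas poorly differentiated carcinoma 2 came from 1 animal, and the 15 tumours from 13 animals. The number of arrays limits the precision of every difference, and all values are on the log2 scale unless given as fold differences.

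Principal component 1 separated the Neu tumours, with a mean score of -52.5 ± 12.7 (SD, n = 3), from the KRas tumours at 60.6 ± 25.5 (n = 4). The R26KRas adenocarcinomas at -11.4 ± 3.99 and the R26KRas poorly differentiated carcinomas at -9.90 ± 19.5 (n = 4 each) lay between them. KRas tumours varied most among themselves, with a median SD per gene of 0.247 against 0.186 in Neu tumours, 0.187 in R26KRas adenocarcinomas and 0.179 in R26KRas poorly differentiated carcinomas. KRas tumour 2 lay closest to the R26KRas tumours, at 29.6. Its correlation across genes was 0.951, 0.959 and 0.952 with KRas tumours 1, 3 and 4, and 0.952 to 0.970 with the R26KRas tumours.

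**Figure D1:**
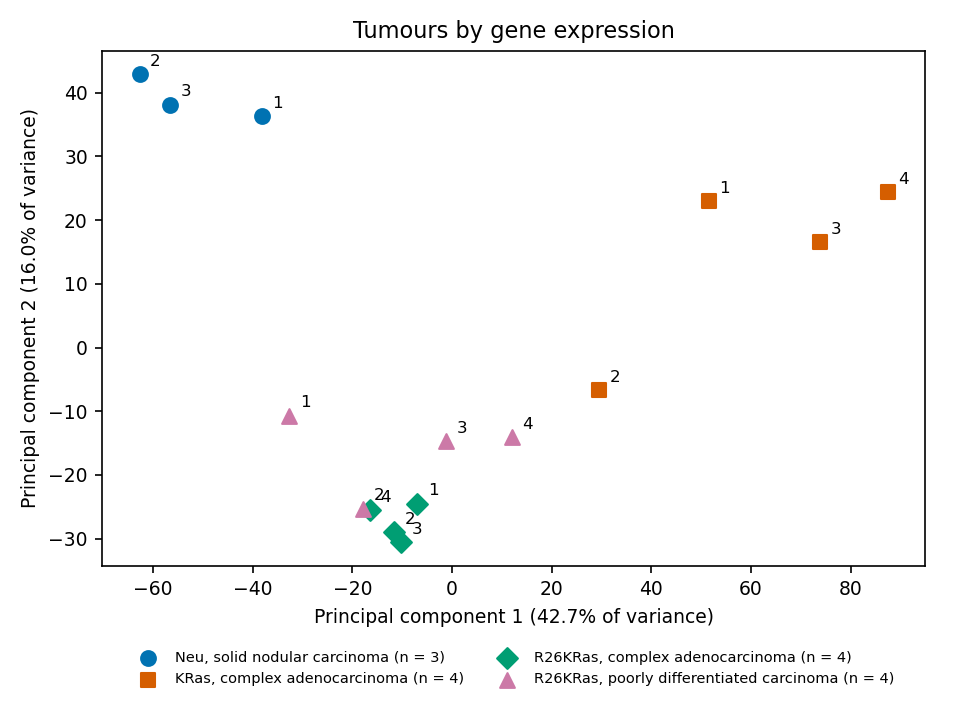
Scores of the 15 tumours on principal components 1 and 2 of gene expression, without unit, with the share of variance each holds on its axis; each point is 1 tumour, its number is the replicate, and shape and colour give the group. The 3 Neu tumours, the 4 KRas tumours and the 8 R26KRas tumours fall apart; on component 2 the R26KRas adenocarcinomas (-30.6 to -24.5) lie below poorly differentiated carcinomas 1, 3 and 4 (-14.7 to -10.7), with carcinoma 2 (-25.3), of the same animal as adenocarcinomas 1 and 4, among them.

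The first comparison set KRas tumours (n = 4) against Neu tumours (n = 3), which differ in genotype and in pathology. The alveolar and milk list score was lower in KRas tumours, least so in KRas tumour 2. Neutrophil, fibroblast and, except in KRas tumour 1, squamous list scores were higher. None of these lists passed with an estimated correlation (adjusted p = 0.272 to 0.303). Lalba, which encodes the milk protein alpha-lactalbumin, fell from a mean log2 level of 12.91 ± 0.201 (SD) to 6.58 ± 1.72, a difference of -6.33 (SE 0.653, adjusted p = 1.8e-05). Klk6, a kallikrein-related serine protease, rose from 4.62 ± 0.095 to 10.30 ± 0.506, a difference of 5.68 (SE 0.546, adjusted p = 1.08e-05). Erbb2, the gene that the Neu transgene encodes, fell from 11.37 ± 0.334 to 8.27 ± 0.257, an 8.58-fold difference (log2 SE 0.225, adjusted p = 1.21e-06). Array signal from the transgene and from the mouse gene cannot be separated here. Of 22180 genes, 5964 (26.9%) passed, 2625 of them higher and 3339 lower in KRas tumours, and 2655 of these differed at least 2-fold (1469 higher, 1186 lower). An unadjusted p under 0.05 was reached by 8096 genes, against 1109 expected by chance. The groups did not overlap for 29.1% of genes, where chance gives 5.71%.

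**Figure D2:**
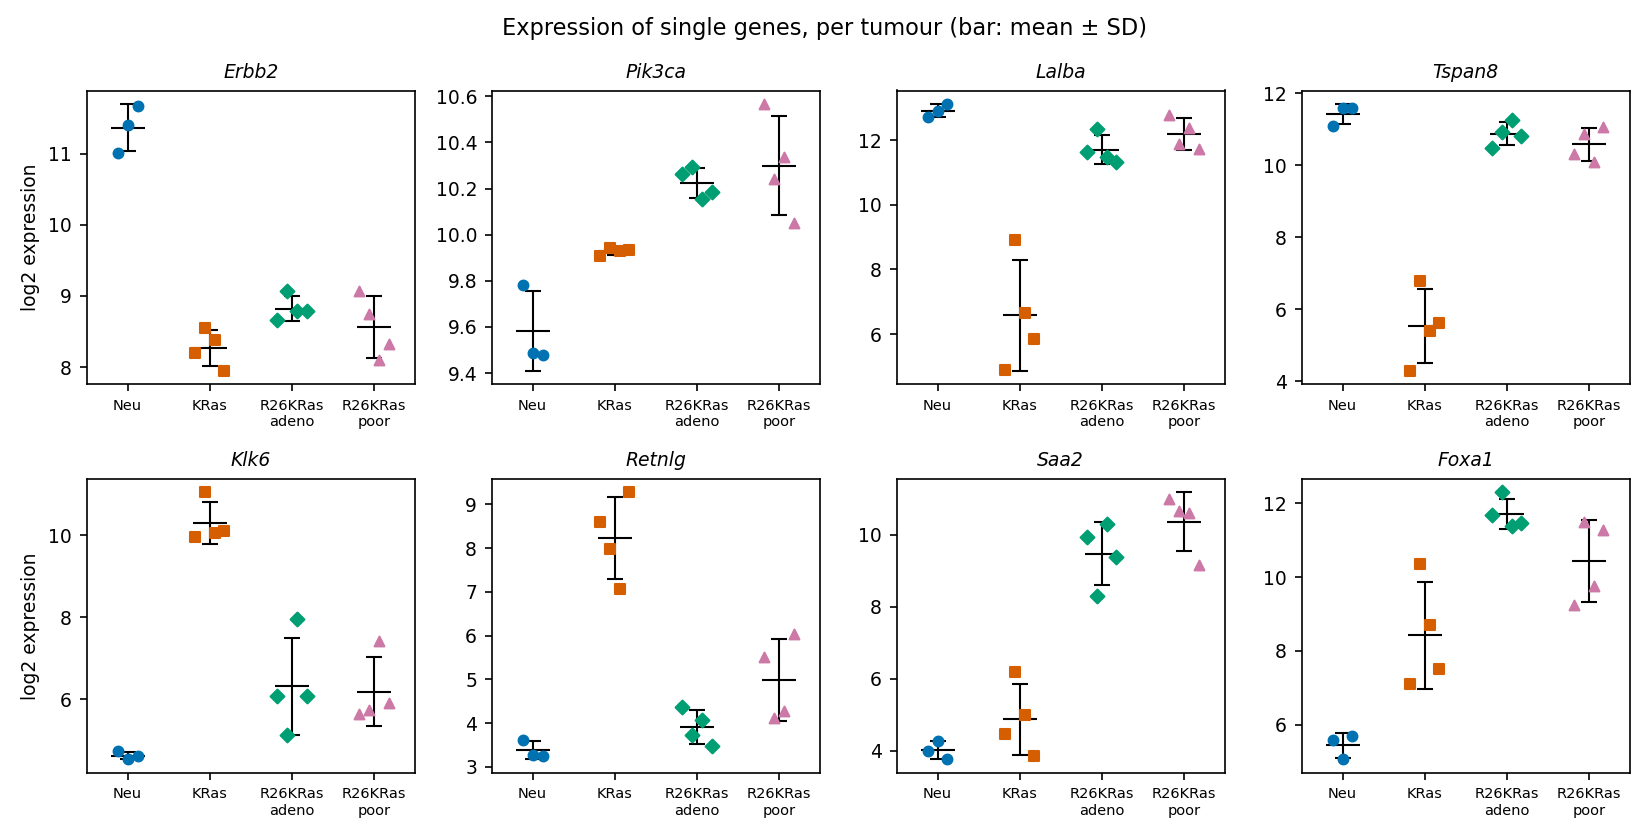
Log2 expression (vertical axes) of 8 genes in the Neu tumours (n = 3), KRas tumours (n = 4), R26KRas adenocarcinomas (n = 4) and R26KRas poorly differentiated carcinomas (n = 4); each point is 1 tumour and bars give mean ± SD. Lalba and Tspan8 average 6.58 and 5.52 in KRas tumours against 12.91 and 11.42 in Neu tumours, and Foxa1 is lowest in Neu tumours at 5.44 and highest in R26KRas adenocarcinomas at 11.71.

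The alveolar and milk list fell as a group in KRas tumours: 13 of 19 measured members fell, 1 rose and 5 did not pass (median log2 difference -2.28, camera adjusted p = 9.21e-05; adjusted p = 0.303 with an estimated correlation). When adjusted over the list alone, 14 fell and 1 rose. Casein genes varied widely between KRas tumours: Csn1s2a fell 93.6-fold (log2 SE 1.56, adjusted p = 0.00625), Csn1s1 64-fold (log2 SE 1.33, adjusted p = 0.00394) and Csn2 60.8-fold (log2 SE 1.86, adjusted p = 0.0282). Csn2 kept its call only when KRas tumour 2 was the one left out. Without Neu tumours 1, 2 and 3 its adjusted p was 0.0843, 0.0626 and 0.0709, and without KRas tumours 1, 3 and 4 it was 0.0703, 0.0552 and 0.0765. The member that rose was Aldh1a3, a retinaldehyde dehydrogenase (2.41). Tspan8, a tetraspanin of epithelial cell surfaces, fell 59.6-fold (log2 -5.90, SE 0.426, adjusted p = 1.2e-06). Among tight junction and adhesion genes 15 of 20 fell, none rose and 5 did not pass, with the same counts when adjusted over the list alone (median -1.37, camera adjusted p = 9.34e-08; adjusted p = 0.303 with an estimated correlation). They included Marveld3, a tight junction membrane protein (-2.91, SE 0.388, adjusted p = 0.000108), and the claudins Cldn3 (-2.62, SE 0.375, adjusted p = 0.000178) and Cldn8 (-2.45, SE 0.51, adjusted p = 0.00255). Luminal epithelium genes moved both ways, 3 up, 4 down and 10 not passing (3 up and 5 down when adjusted over the list alone; camera adjusted p = 0.341). Foxa1 (2.98) and Krt19 (2.48) rose, and the luminal regulators Gata3 (-2.40) and Elf5 (-2.84) fell.

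Squamous differentiation genes were higher in KRas tumours: 14 of 22 rose, none fell and 8 did not pass, or 15 when adjusted over the list alone (median 2.52, camera adjusted p = 6.86e-08; adjusted p = 0.303 with an estimated correlation). Sprr1a, a precursor of the cornified envelope, rose by 6.01 (SE 1.31, adjusted p = 0.00349) and Dsg3, a desmosomal cadherin, by 4.91 (SE 0.878, adjusted p = 0.00086). KRas tumour 1 stood apart. Its squamous list score was -1.13, against 1.62 to 3.35 in the other KRas tumours and -1.25 to -1.20 in Neu tumours. Its Klk6 level of 9.96 lay close to the 10.06 to 11.05 of the others, so not every member was low. Tmprss11e, a transmembrane serine protease of stratified epithelia, rose by 5.19 (SE 0.525, adjusted p = 1.62e-05). Basal and myoepithelial genes rose for 13 of 18 members, fell for 1 and did not pass for 4, with the same counts when adjusted over the list alone (median 1.67, camera adjusted p = 6.7e-07; adjusted p = 0.272 with an estimated correlation). Krt14 (3.98), Col17a1 (3.41) and the smooth muscle actin gene Acta2 (1.85) rose, and Oxtr, the oxytocin receptor of myoepithelial cells, fell (-2.26, adjusted p = 0.00873, and 0.0501 without Neu tumour 1). The basal score of KRas tumour 1 was -0.837, near the -1.56 to -0.891 of Neu tumours and apart from the 0.461 to 0.759 of the other KRas tumours. Krt14 and Col17a1 were 6.92 and 6.51 in that tumour. In every fit that left out 1 tumour, 7 of the 14 basal and 9 of the 14 squamous genes passed.

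Mesenchymal and EMT genes rose for 16 of 18 members, with none falling and 2 not passing, over all genes and when adjusted over the list alone (median 2.46, camera adjusted p = 1.36e-11; adjusted p = 0.272 with an estimated correlation). Cdh11, a mesenchymal cadherin, rose by 3.83 (SE 0.675, adjusted p = 0.000785), fibronectin (Fn1) by 3.74 (SE 0.798, adjusted p = 0.00299) and the transcription factor Zeb1 by 1.61. Tenascin C (Tnc) rose by 3.47 (SE 0.978, adjusted p = 0.0163) but did not pass without Neu tumour 2 (0.0902) or Neu tumour 3 (0.0627), or in a fit of the 7 tumours alone (0.083). In the fibroblast and collagen list 18 of 19 members rose, none fell and 1 did not pass, with the same counts when adjusted over the list alone (median 2.50, camera adjusted p = 6.42e-11; adjusted p = 0.303 with an estimated correlation). Lum (3.39, SE 1.13, adjusted p = 0.0381), Dcn (3.38, SE 1.17, adjusted p = 0.0458) and Col3a1 (3.25, SE 0.847, adjusted p = 0.0105) rose, as did Col6a3 (2.91). Without Neu tumour 2 the differences of Lum, Dcn and Col3a1 were 2.12, 1.45 and 2.31, and their adjusted p was 0.22, 0.251 and 0.0713. Lum also failed without Neu tumour 3 (0.0648), and both proteoglycan genes failed without KRas tumour 2 (Lum 0.0562, Dcn 0.0708), 3 (0.084, 0.0961) or 4 (0.101, 0.107). Both ended as well in a fit of the 7 tumours alone (0.067, 0.146) and without the 3 R26KRas tumours of 1 animal (0.0679, 0.0917), and Dcn with eBayes trend (0.0519) or averaging of that animal's adenocarcinomas (0.0575). Mmp13, an interstitial collagenase, rose by 5.46 (SE 0.901, adjusted p = 0.000494). Endothelial genes shifted less: 4 of 15 rose, including Cldn5 (0.83), none fell and 11 did not pass, or 7 rose when adjusted over the list alone (median 0.70, camera adjusted p = 0.000243; adjusted p = 0.303 with an estimated correlation). Of the 4, 2 passed in every fit that left out 1 tumour.

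Neutrophil genes rose for 14 of 15 members, none fell and 1 did not pass, with the same counts when adjusted over the list alone (median 3.06, camera adjusted p = 3.33e-11; adjusted p = 0.272 with an estimated correlation). Stfa2l1, a stefin A family protease inhibitor, rose by 5.51 (SE 0.742, adjusted p = 0.000116), interleukin 1 beta (Il1b) by 5.09 (SE 0.434, adjusted p = 4.63e-06) and Retnlg, a neutrophil resistin-like gene, by 4.85 (SE 0.494, adjusted p = 1.69e-05). Of 18 macrophage and monocyte genes 16 rose, none fell and 2 did not pass, again the same when adjusted over the list alone (median 1.81, camera adjusted p = 4.77e-10; adjusted p = 0.272 with an estimated correlation). The scavenger receptor Msr1 rose by 3.05 (SE 0.538, adjusted p = 0.000778), the chemokine receptor Ccr2 by 2.85 (SE 0.54, adjusted p = 0.00133) and the mannose receptor Mrc1 by 3.01 (SE 0.744, adjusted p = 0.00768, and 0.0535 without Neu tumour 2). MHC class II and dendritic genes rose for 7 of 12 members, including H2-Ab1 (3.37), and fell for none, or rose for 9 when adjusted over the list alone (median 1.34, camera adjusted p = 2.53e-05; adjusted p = 0.272 with an estimated correlation). T and NK cell genes rose for 8 of 19 members, including Ccl5 (1.12), and fell for none, or rose for 10 when adjusted over the list alone (median 0.54, camera adjusted p = 0.00174; adjusted p = 0.303 with an estimated correlation). B and plasma cell genes passed as a list (median 0.92, camera adjusted p = 0.0128; adjusted p = 0.435 with an estimated correlation) with 1 rise (Cd22, 1.72), 1 fall (Derl3, -1.81) and 12 not passing, over all genes and when adjusted over the list alone. Derl3, which acts in protein degradation at the endoplasmic reticulum, lost its call in 2 of the 7 fits that left out 1 tumour, with up to 0.0591 without Neu tumour 2. The call of the list ended with fry (0.0732), array weights (0.126), the stricter filter on dim genes (0.122) and without KRas tumour 2 (0.114). The list score of KRas tumour 2 was 1.81, against -0.30 to 0.57 in the other KRas tumours. Interferon response genes fell for 4 of 16 members, including Rtp4 (-2.32), and rose for none, or fell for 5 when adjusted over the list alone (median -0.98, camera adjusted p = 0.0216; adjusted p = 0.564 with an estimated correlation). Without KRas tumour 2 (0.0727), with fry (0.0732) or with the stricter filter (0.0601) the list did not pass. In every fit that left out 1 tumour, 3 of the 8 T and NK cell genes and 2 of the 4 interferon genes passed.

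Among metabolic and signalling lists, fatty acid and sterol synthesis fell for 7 of 14 members, rose for 1 and did not pass for 6, or fell for 8 and rose for 1 when adjusted over the list alone (median -0.69, camera adjusted p = 0.00503; adjusted p = 0.303 with an estimated correlation). The lipogenic regulator Srebf1 (-2.51) and the desaturase Scd1 (-2.33) fell and Hmgcs1, a sterol pathway synthase, rose (0.73). Immediate early and stress genes rose for 6 of 18 members, including Egr2 (2.01), and fell for 2, including Nr4a1 (-1.73), with the same counts when adjusted over the list alone (median 0.52, camera adjusted p = 0.00794; adjusted p = 0.303 with an estimated correlation). In the Notch list 6 of 16 rose, including the ligand Jag1 (3.65), and 2 fell, including the target Hey1 (-3.48), with the same counts when adjusted over the list alone (median 0.34, camera adjusted p = 0.0257; adjusted p = 0.303 with an estimated correlation). Notch genes did not pass without KRas tumour 3 (0.0636) or with the stricter filter (0.0598). In the Wnt list 3 of 17 rose, including Lgr5 (2.59), and Rnf43 fell (-2.30), or 5 rose and 1 fell when adjusted over the list alone (median 0.22, camera adjusted p = 0.0346; adjusted p = 0.272 with an estimated correlation). The Wnt call ended without Neu tumour 1 (0.0748) or KRas tumour 2 (0.0899), and with quantile normalization (0.0538), the looser filter (0.0534) or array weights (0.124). Lists that did not pass were ERK pathway output (3 up, 6 down of 19, camera adjusted p = 0.776), FOXO-activated genes (2 up, 7 down of 15, 0.0928), glycolysis and hypoxia (1 up, 3 down of 16, 0.588), cell cycle (0 of 24, 0.381), adipocyte (2 up of 14, 0.49), skeletal muscle (1 down of 15, 0.84), mast cell (1 up, 1 down of 10, 0.615), nerve and Schwann cell (1 up, 3 down of 7, 0.233) and the 2 measured driver genes (0.381). Without KRas tumour 2 the FOXO and cell cycle lists passed, both lower (0.0474 and 0.00417). With array weights the cell cycle list passed as well (0.00269), and by fry the FOXO (0.00182), driver gene (0.000334) and nerve and Schwann cell lists (0.00289). With fry, which asks whether the genes of a list move one way without comparing them with other genes, 18 of the 27 lists passed.

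Pik3ca was 0.35 higher in KRas than in Neu tumours (SE 0.122, adjusted p = 0.0487) and the groups did not overlap. Its call ended in 6 of the 7 fits that left out 1 tumour, at 0.165 and 0.171 without Neu tumours 2 and 3 and at 0.0659, 0.0698, 0.0863 and 0.0886 without KRas tumours 1, 2, 3 and 4. It also ended with centred arrays (0.112), in a fit of the 7 tumours alone (0.106), with the animal as a random block (0.0589), with averaging (0.0599) and without the 3 tumours of 1 animal (0.0982). For 24 of the 27 genes named for this comparison by the fixed rule the groups did not overlap, Tnc, Lum and Dcn being the exceptions. The rule took the 5 largest rises and 5 largest falls only from genes without overlap, so it fixes part of this count. Differences were tested with limma's moderated test in a fit of all 15 tumours. A fit of the 7 tumours alone gave 3910 genes. Stfa2l1 (3.28), Retnlg (3.38), Dsg3 (4.55), Klk6 (4.62), Tmprss11e (4.67) and Sprr1a (4.82) had means in Neu tumours near or below the arrays' lower quartiles (4.36 to 4.57), and no background was measured, so their differences are of array signal and not measured ratios of RNA.

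**Figure D3:**
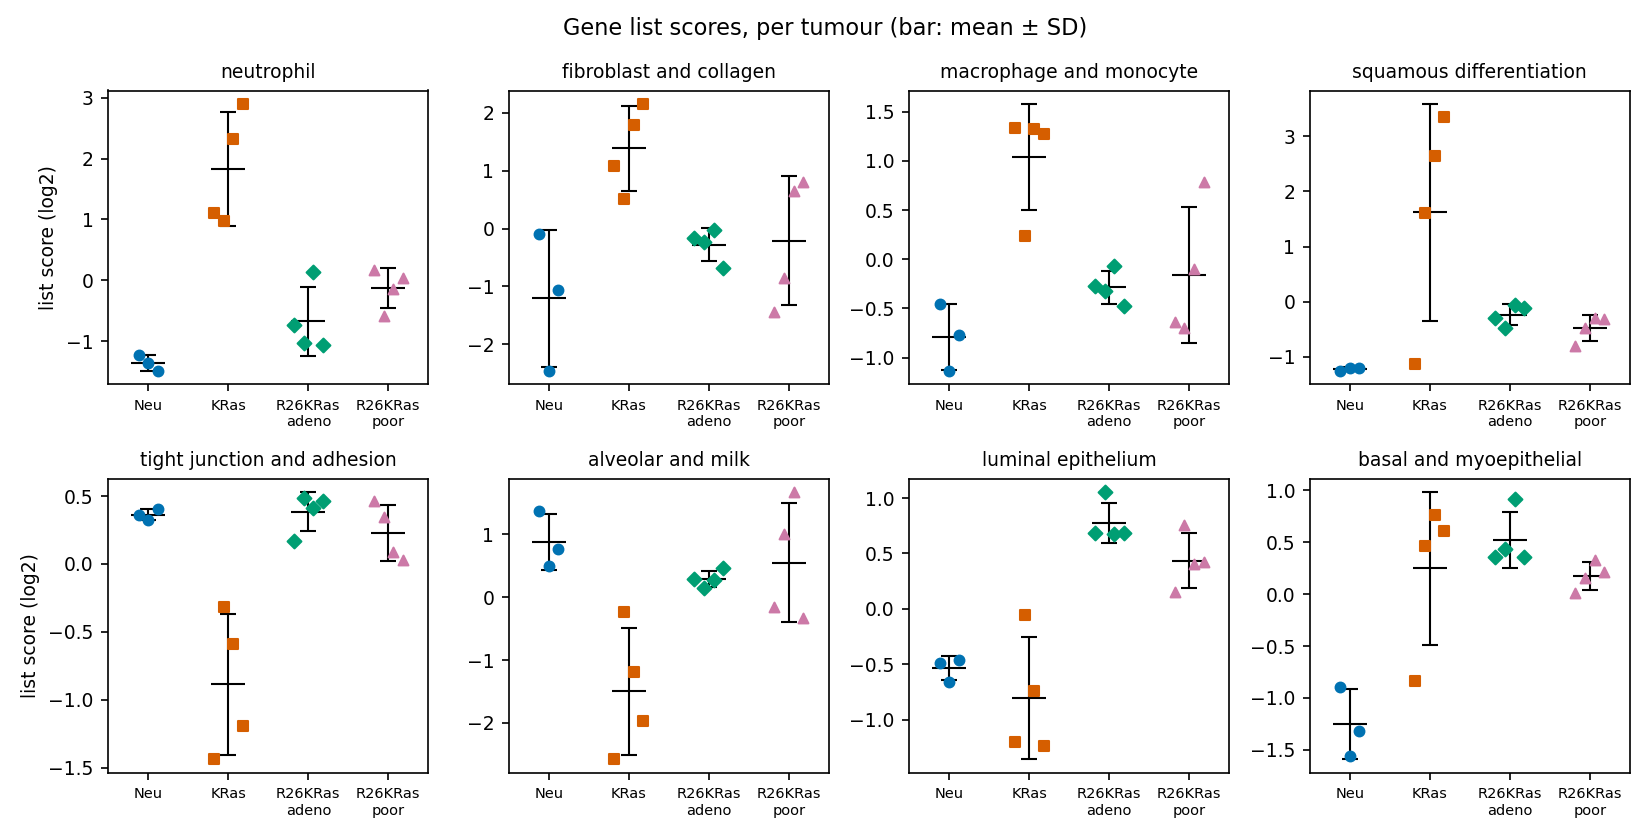
Scores of 8 gene lists (mean over a list's genes of the log2 deviation from the mean of all tumours, vertical axes) in the 4 groups (n = 3, 4, 4 and 4); each point is 1 tumour and bars give mean ± SD. Neutrophil scores of the 4 KRas tumours run from 0.972 to 2.90, above every other tumour, and KRas tumour 1 lies with the Neu tumours in the squamous list at -1.13.

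The next comparison asked what adding R26(H1047R/+) went with at the same pathology term, in R26KRas adenocarcinomas against KRas tumours (n = 4 each). Milk, luminal and tight junction genes were higher as lists with the added allele, and neutrophil, macrophage and fibroblast genes lower, although not every member passed. None of these lists passed with an estimated correlation (adjusted p = 0.227 to 0.269). Tspan8 rose 40.8-fold, from 5.52 ± 1.03 to 10.88 ± 0.322 (log2 SE 0.394, adjusted p = 6.77e-06), and Lalba 34.8-fold, from 6.58 ± 1.72 to 11.70 ± 0.447 (log2 SE 0.604, adjusted p = 0.000221). Saa2, an acute phase serum amyloid gene, rose by 4.60, from 4.88 ± 0.991 to 9.47 ± 0.872 (SE 0.513, adjusted p = 0.000143). Retnlg fell by 4.31 (SE 0.457, adjusted p = 9.81e-05), to a level of 3.92, below the arrays' lower quartiles. In all, 3274 of 22180 genes (14.8%) passed, 1943 higher and 1331 lower in R26KRas adenocarcinomas, and 1328 of these differed at least 2-fold (630 higher, 698 lower). An unadjusted p under 0.05 was reached by 6391 genes, and the groups did not overlap for 16.5% of genes, where chance gives 2.86%.

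Tight junction and adhesion genes rose for 15 of 20 members, with none falling and 5 not passing, or for 17 when adjusted over the list alone (median 1.22, camera adjusted p = 3.93e-13; adjusted p = 0.237 with an estimated correlation). Marveld3 rose by 2.43 (SE 0.359, adjusted p = 0.000803), Cldn3 by 2.17 (SE 0.347, adjusted p = 0.0014) and the membrane serine protease Prss8 by 2.17 (SE 0.28, adjusted p = 0.000356). Luminal epithelium genes rose for 12 of 17 members and fell for none, or rose for 16 when adjusted over the list alone (median 1.31, camera adjusted p = 4.61e-10; adjusted p = 0.227 with an estimated correlation). Foxa1, a pioneer factor of luminal cells, rose by 3.29 (SE 0.62, adjusted p = 0.00363), Krt19 by 2.89 (SE 0.501, adjusted p = 0.00226) and the alveolar regulator Elf5 by 2.84 (SE 0.505, adjusted p = 0.00256). Alveolar and milk genes rose for 10 of 19 members and fell for none, or rose for 11 when adjusted over the list alone (median 1.55, camera adjusted p = 4.27e-06; adjusted p = 0.237 with an estimated correlation). Pinc, a noncoding RNA of the mammary gland, rose by 4.86 (SE 0.841, adjusted p = 0.00224) and Elapor1, an endosome and lysosome regulator, by 4.72 (SE 0.563, adjusted p = 0.000239). Basal and myoepithelial genes did not pass as a list (2 up of 18, camera adjusted p = 0.405), with Oxtr up by 3.62.

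Neutrophil genes fell for 12 of 15 members and rose for none, or fell for 13 when adjusted over the list alone (median -2.35, camera adjusted p = 7.21e-13; adjusted p = 0.237 with an estimated correlation). Stfa2l1 fell by 4.49 (SE 0.687, adjusted p = 0.00103) and the lectin receptor Clec4d by 3.25 (SE 0.459, adjusted p = 0.000584). Macrophage and monocyte genes fell for 13 of 18 members and rose for none, or fell for 15 when adjusted over the list alone (median -1.43, camera adjusted p = 2.21e-09; adjusted p = 0.237 with an estimated correlation). Among them were Msr1 (-2.17, SE 0.498, adjusted p = 0.0108), lysozyme 2 (Lyz2, -2.05, SE 0.451, adjusted p = 0.00857) and Ms4a7 (-1.76, SE 0.352, adjusted p = 0.00511). Fibroblast and collagen genes fell for 11 of 19 members and rose for none, or fell for 16 when adjusted over the list alone (median -1.80, camera adjusted p = 2.21e-09; adjusted p = 0.269 with an estimated correlation). Among the members that passed, the largest falls were in Pdgfra (-2.32, SE 0.48, adjusted p = 0.00618), Fbln1 (-2.07, SE 0.473, adjusted p = 0.0106) and Col6a3 (-2.05, SE 0.4, adjusted p = 0.00439). Without the 3 tumours of 1 animal, which leaves 2 adenocarcinomas, 7 of the 12 neutrophil genes, 1 of the 13 macrophage genes and 1 of the 11 fibroblast genes still passed. Among the other lists 12 of 15 tight junction, 7 of 12 luminal and 5 of 10 milk genes did. Msr1 (0.0757), Lyz2 (0.0894), Ms4a7 (0.0745), Pdgfra (0.0649), Fbln1 (0.106) and Col6a3 (0.0619) did not.

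Squamous differentiation genes fell for 6 of 22 members and rose for none, or fell for 11 when adjusted over the list alone (median -1.75, camera adjusted p = 1.88e-07; adjusted p = 0.28 with an estimated correlation). Klk6 fell by 3.99 (SE 0.506, adjusted p = 0.000327). The score of KRas tumour 1 (-1.13) lay below every R26KRas adenocarcinoma (-0.474 to -0.0564), against the direction of the list. Of the 6 genes, 2 passed in every fit that left out 1 tumour and 1 passed without the 3 tumours of 1 animal. Krtdap, a keratinocyte differentiation gene (-3.11, SE 0.894, adjusted p = 0.0311), failed without KRas tumour 2 (0.0587), 3 (0.091) or 4 (0.105), without R26KRas adenocarcinoma 2 (0.084), 3 (0.0689) or 4 (0.0676), and without the 3 tumours of 1 animal (0.117). In a fit of the 8 tumours alone and with averaging it was also above the threshold (0.117 and 0.0537). Sprr1b (-3.04, SE 0.853, adjusted p = 0.0282) failed without KRas tumour 3 (0.0884) or 4 (0.0951), without R26KRas adenocarcinoma 1 (0.0583), 2 (0.0735) or 4 (0.0605), and without the 3 tumours of 1 animal (0.151). Those 2 alternatives ended its call as well (0.105 and 0.0587). Outside the lists, Tmprss11e fell by 4.21 (SE 0.486, adjusted p = 0.000184) and the chemokine Cxcl3 by 3.83 (SE 0.92, adjusted p = 0.0137, with 0.092 without the 3 tumours of 1 animal and 0.0689 in a fit of the 8 tumours alone). Cxcl3 averaged 2.90 and Stfa2l1 4.30 in R26KRas adenocarcinomas, and Pinc 4.73 and Saa2 4.88 in KRas tumours. These lay below or near the arrays' lower quartiles, so the 4 were differences of array signal as well.

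Glycolysis and hypoxia genes rose for 5 of 16 members and fell for none, or rose for 7 when adjusted over the list alone (median 0.71, camera adjusted p = 2.96e-05; adjusted p = 0.309 with an estimated correlation). The carbonic anhydrase Car9 rose by 2.04 and lactate dehydrogenase A (Ldha) by 1.20. The list score of KRas tumour 1 (0.174) lay within the range of R26KRas adenocarcinomas (0.0584 to 0.67). It stood apart from the other KRas tumours (-0.764 to -0.628). Fatty acid and sterol synthesis genes rose for 6 of 14 members and fell for none, or rose for 9 when adjusted over the list alone (median 0.55, camera adjusted p = 3.18e-06; adjusted p = 0.237 with an estimated correlation). Malic enzyme (Me1) rose by 2.12 and Scd1 by 1.99. Mesenchymal and EMT genes fell for 7 of 18 members and rose for none, or fell for 12 when adjusted over the list alone (median -0.96, camera adjusted p = 2.25e-06; adjusted p = 0.269 with an estimated correlation). Twist1 fell by 1.58 and Zeb1 by 1.48. Lower as lists were also endothelium (5 of 15 down, median -0.68, camera adjusted p = 5.86e-07), T and NK cell (6 of 19 down, median -0.41, 2.72e-05) and MHC class II and dendritic genes (3 of 12 down, median -0.97, 6.6e-05), each with an adjusted p = 0.237 with an estimated correlation. Adjusted over the list alone, 10, 8 and 8 of these genes fell. Without the 3 tumours of 1 animal 1 of the 5 endothelial, 2 of the 6 T and NK cell, 0 of the 3 MHC class II and 2 of the 7 mesenchymal genes passed. B and plasma cell genes passed as a list with 1 member, Cd22, down (median -0.70, camera adjusted p = 0.00103; adjusted p = 0.309 with an estimated correlation). This call ended without KRas tumour 2 (0.0809), with fry (0.0625), with the stricter filter on dim genes (0.0506) and with array weights (0.0608). Interferon response genes were higher, with 2 of 16 up over all genes and 4 when adjusted over the list alone (median 0.76, camera adjusted p = 0.00498; adjusted p = 0.536 with an estimated correlation). That call ended without KRas tumour 2 (0.0564), R26KRas adenocarcinoma 1 (0.0789) or the 3 tumours of 1 animal (0.144), and with fry (0.108) or the stricter filter (0.0728). None of 24 cell cycle genes passed and the list lay just above the threshold (median 0.42, camera adjusted p = 0.0562). It passed without KRas tumour 1 (0.026) or 2 (3.13e-05) and without R26KRas adenocarcinoma 2 (0.00786) or 3 (0.00453), with array weights (3.35e-06) and with all 8 R26KRas tumours (0.0155). The remaining 10 lists did not pass by camera, the adipocyte list doing so, lower, only without KRas tumour 1 (0.0418). By fry, 15 of the 27 lists passed, among them the driver gene (0.0122) and nerve and Schwann cell lists (0.0105), which camera did not call.

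Erbb2 was 0.55 higher in R26KRas adenocarcinomas than in KRas tumours (adjusted p = 0.0913) and Pik3ca 0.30 higher (adjusted p = 0.0961). Neither passed, although the groups did not overlap for either. Adjusted over the list of these 2 driver genes alone both passed, as did the list by fry (0.0122), but not by camera (0.141). With all 8 R26KRas tumours against the KRas tumours, Pik3ca passed (adjusted p = 0.0282), as it did with array weights (0.0441). Over all alternatives its adjusted p ran from 0.0282 to 0.278. Array signal from the added allele, taken here as Pik3ca, and from the gene's own locus cannot be separated. For 23 of the 25 named genes that passed the groups did not overlap, Krtdap and Sprr1b being the exceptions. Part of this count is again fixed by the naming rule. The count of 3274 fell to 2156 without KRas tumour 3, 1847 without KRas tumour 4, 2148 without R26KRas adenocarcinoma 2, 2121 without R26KRas adenocarcinoma 4 and 1162 without the 3 tumours of 1 animal. It was 2031 in a fit of the 8 tumours alone and 5870 with array weights.

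Within the R26KRas genotype, poorly differentiated carcinomas were compared with adenocarcinomas (n = 4 each), and no gene separated the pathology groups past the threshold. The smallest unadjusted p among lower genes belonged to Clca1, a secreted regulator of chloride conductance, at -1.17 (SE 0.246), followed by the hepcidin gene Hamp2 (-0.74, SE 0.158), calponin 1 (Cnn1, -1.35, SE 0.304), the phosphatase Ptpn14 (-0.59, SE 0.136) and Cbs, cystathionine beta-synthase (-0.49, SE 0.12). Among higher genes they were Gpx6, a glutathione peroxidase (0.65, SE 0.167), the histone gene H2bc9 (0.78, SE 0.199), Pspn, a GDNF family ligand (0.51, SE 0.131), the homeobox gene Dbx2 (0.45, SE 0.122) and the aquaporin Aqp12 (0.33, SE 0.0904). All 10 had an adjusted p = 1, and the groups did not overlap for any of them except Gpx6. Hamp2, Gpx6, H2bc9 and Dbx2 averaged 2.82, 4.01, 3.82 and 4.26 in adenocarcinomas. These levels lay below the arrays' lower quartiles (4.36 to 4.57), so their differences are of array signal. Erbb2 differed by -0.26 (SE 0.209) and Pik3ca by 0.08 (SE 0.113), neither past the threshold, and the largest difference of any gene was 2.38. By limma, 0 of 22180 genes passed and 592 had an unadjusted p under 0.05, where chance gives 1109, and every alternative fit also gave 0. The groups did not overlap for 2.19% of genes, where chance gives 2.86%.

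Skeletal muscle (median 0.40, camera adjusted p = 7.61e-06), interferon response (0.43, 3.76e-05), neutrophil (0.43, 0.000197) and mast cell genes (0.23, 0.00393) were higher as lists in poorly differentiated carcinomas, and basal and myoepithelial (-0.20, 0.000389) and luminal epithelium genes (-0.17, 0.00465) lower. No member of these 6 lists passed over all genes, and 1 did when adjusted over the list alone, a basal gene lower in poorly differentiated carcinomas. Each of the 6 had an adjusted p = 0.497 with an estimated correlation, and by fry 0 of 27 lists passed. The skeletal muscle call ended without R26KRas poorly differentiated carcinoma 3 (0.123), the mast cell call without carcinoma 3 (0.0974) or 4 (0.116), and the luminal call without R26KRas adenocarcinoma 2 (0.121). With the animal as a random block the mast cell and luminal lists both had an adjusted p = 0.284. Of the 21 lists that did not pass, 14 did so in at least 1 fit that left out a tumour. Simulated differences of 4-fold were found for 94.5% of genes in this comparison and those of 1.5-fold for 31.9%.

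The last comparison set the R26KRas tumours (n = 8, both pathology groups weighted equally) against the Neu tumours (n = 3), again with genotype and pathology changing together. The luminal genes Foxa1 and Krt19 were higher in R26KRas tumours, whereas milk genes did not pass as a list. Foxa1 rose 49.6-fold from 5.44 ± 0.34 in Neu tumours to 11.71 ± 0.411 in adenocarcinomas and 10.44 ± 1.11 in poorly differentiated carcinomas (log2 SE 0.593, adjusted p = 4.35e-05). Krt19 rose 34.9-fold (log2 5.12, SE 0.48, adjusted p = 1.93e-05), and Saa2 by 5.89 (SE 0.492, adjusted p = 6.93e-06). Saa2 averaged 4.02 in Neu tumours, below the arrays' lower quartiles (4.36 to 4.57), so its difference is one of array signal. Erbb2 fell by 2.68 (SE 0.2, adjusted p = 2.81e-06) and Pik3ca rose by 0.68 (SE 0.108, adjusted p = 0.000961), both without overlap between groups. Array signal of the Neu transgene and of the added allele, taken as Pik3ca, cannot be told from that of the genes' own loci. In total 2331 of 22180 genes (10.5%) passed, 1190 higher and 1141 lower in R26KRas tumours, 877 of them at least 2-fold (529 higher, 348 lower). The groups did not overlap for 14% of genes, where chance gives 1.21%, and 5237 genes had an unadjusted p under 0.05.

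Other large rises in R26KRas tumours were Lipm, an epidermal lipase (6.05, SE 0.588, adjusted p = 2.37e-05), and Sprr1a (5.61, SE 1.16, adjusted p = 0.00613, and 0.0506 without the 3 tumours of 1 animal). Lipm (4.59), Sprr1a (4.82), Krt17 (4.78) and Pgr (4.49) also averaged near the arrays' lower quartiles in Neu tumours. The largest falls were Cabcoco1 (-5.35, SE 0.262, adjusted p = 6.64e-08), the matrix protein gene Comp (-4.61, SE 0.686, adjusted p = 0.000606), the mitochondrial carrier Slc25a34 (-4.50, SE 0.209, adjusted p = 6.32e-08), the fatty acid translocase Cd36 (-4.40, SE 0.981, adjusted p = 0.00975) and the NADPH oxidase Duox1 (-4.10, SE 0.406, adjusted p = 2.68e-05). Cd36 did not pass without Neu tumour 1 (0.0555).

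Basal and myoepithelial genes rose for 11 of 18 members in R26KRas tumours and fell for none, or rose for 15 when adjusted over the list alone (median 1.44, camera adjusted p = 4.58e-12; adjusted p = 0.217 with an estimated correlation). Col17a1, a hemidesmosomal collagen, rose by 3.57 (SE 0.515, adjusted p = 0.000476). The keratins Krt14 (3.35, SE 0.839, adjusted p = 0.0193) and Krt17 (3.20, SE 0.787, adjusted p = 0.0172) rose as well. Krt14 failed without Neu tumour 1 (0.06), 2 (0.086) or 3 (0.0712), with differences of 3.32, 3.31 and 3.41. Krt17 failed without Neu tumour 2 (0.104) or 3 (0.0823), with differences of 2.90 and 3.08. Mesenchymal and EMT genes rose for 8 of 18 members and fell for none, or rose for 11 when adjusted over the list alone (median 1.10, camera adjusted p = 4.76e-08; adjusted p = 0.304 with an estimated correlation). They included the transcription factor Snai2 (3.11, SE 0.449, adjusted p = 0.000476) and N-cadherin (Cdh2, 2.76, SE 0.334, adjusted p = 0.000128). Tnc (2.89, SE 0.867, adjusted p = 0.0473) lost its call in 9 of the 11 fits that left out 1 tumour, at 0.261 and 0.172 without Neu tumours 2 and 3. Without R26KRas adenocarcinomas 1, 2, 3 and 4 it was 0.0688, 0.0791, 0.0718 and 0.0607, and without R26KRas poorly differentiated carcinomas 2, 3 and 4 it was 0.0603, 0.0809 and 0.0781. Other alternatives put it between 0.0506 with centred arrays and 0.11 without the 3 tumours of 1 animal where its call ended. Luminal epithelium genes rose for 7 of 17 members and fell for 1 (Epcam), or rose for 8 and fell for 1 when adjusted over the list alone (median 0.74, camera adjusted p = 0.000145; adjusted p = 0.304 with an estimated correlation). The progesterone receptor gene Pgr (2.54, SE 0.664, adjusted p = 0.0244) failed without Neu tumour 1 (0.0526), 2 (0.11) or 3 (0.0993). Without the 3 tumours of 1 animal Krt14 (0.0723), Krt17 (0.0696) and Pgr (0.124) failed too.

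Immediate early and stress genes rose for 7 of 18 members and fell for 1, or rose for 8 and fell for 2 when adjusted over the list alone (median 0.38, camera adjusted p = 8.25e-05; adjusted p = 0.304 with an estimated correlation). The nuclear receptor gene Nr4a1 fell (-1.22), but not in 6 of the 11 fits that left out 1 tumour, with up to 0.175 without Neu tumour 3. Rises were led by the transcription factors Fos (1.86, SE 0.223, adjusted p = 0.00012), Egr1 (1.60, SE 0.196, adjusted p = 0.000142) and Egr2 (1.47, SE 0.237, adjusted p = 0.00103). Notch pathway genes rose for 5 of 16 members and fell for none, or rose for 7 when adjusted over the list alone (median 0.31, camera adjusted p = 0.000152; adjusted p = 0.304 with an estimated correlation). The ligand Jag1 rose by 3.00 (SE 0.375, adjusted p = 0.000167). FOXO-activated genes fell for 6 of 15 members, including Irs2 (-1.80) and Pik3ip1 (-0.91), and rose for none, or fell for 6 and rose for 1 when adjusted over the list alone (median -0.28, camera adjusted p = 0.0041; adjusted p = 0.304 with an estimated correlation). Glycolysis and hypoxia genes rose for 3 of 16 members and fell for none, or rose for 8 and fell for 1 when adjusted over the list alone (median 0.59, camera adjusted p = 8.25e-05; adjusted p = 0.578 with an estimated correlation). Ndrg1, a hypoxia-responsive gene, rose by 1.56 (SE 0.241, adjusted p = 0.000794). Adm (1.92, SE 0.48, adjusted p = 0.0188) failed without Neu tumour 1 (0.0686), 2 (0.053) or 3 (0.0874), and P4ha1 (1.11, SE 0.277, adjusted p = 0.0189) without Neu tumour 1 (0.086) or 3 (0.0766) or the 3 tumours of 1 animal (0.0729). With the animal as a random block neither passed (Adm 0.0972, P4ha1 0.0713), and by fry the glycolysis and hypoxia list did not (0.0871).

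Fibroblast and collagen genes passed as a list with 2 of 19 members up (median 0.82, camera adjusted p = 0.000138; adjusted p = 0.644 with an estimated correlation). Without Neu tumour 2 it did not (0.0544). The 2 were Postn, which encodes periostin (2.29, SE 0.535, adjusted p = 0.013, with 1.28 and 0.058 without Neu tumour 2 and 0.0581 without the 3 tumours of 1 animal), and Fbln2 (1.09, SE 0.238, adjusted p = 0.0087, and 0.0788 without Neu tumour 3). Neutrophil genes were higher as a list with 1 of 15 up (Il1b, 2.83), or 4 when adjusted over the list alone (median 0.99, camera adjusted p = 0.000668; adjusted p = 0.591 with an estimated correlation). Macrophage and monocyte genes were higher with 1 of 18 up (Cd14, 1.75; median 0.59, camera adjusted p = 0.00142; adjusted p = 0.644 with an estimated correlation). MHC class II and dendritic genes were higher with 4 of 12 up, including H2-Ab1 (2.43), a list call (median 0.38, camera adjusted p = 0.0165; adjusted p = 0.609 with an estimated correlation) that ended without R26KRas poorly differentiated carcinoma 4 (0.051). By fry none of these 4 lists passed, with 0.22 for fibroblast, 0.142 for neutrophil, 0.236 for macrophage and 0.155 for MHC class II genes. Adjusted over the list alone, the fibroblast, macrophage and MHC class II counts were the same. Milk (1 up, 1 down of 19, camera adjusted p = 0.712) and tight junction genes (2 up, 2 down of 20, 0.817) did not pass. The squamous list (4 up of 22, or 5 when adjusted over the list alone, median 0.19, camera adjusted p = 0.0537) passed without R26KRas adenocarcinoma 2 (0.0397) or R26KRas poorly differentiated carcinoma 1 (0.0465). It also passed with 6 other settings, between 0.002 in a fit of the 11 tumours alone and 0.0497 with the mean of a gene's probe sets. The other 13 lists did not pass by camera. By fry 8 of the 27 lists passed, among them the driver gene (0.00508) and Wnt lists (0.0431), which camera did not call. In every fit that left out 1 tumour, 5 of the 11 basal, 4 of the 8 mesenchymal, 4 of the 8 luminal, 5 of the 8 immediate early, 3 of the 5 Notch and 2 of the 6 FOXO genes passed. For 26 of the 28 named genes the groups did not overlap, Adm and Pgr being the exceptions, a count that the naming rule fixes in part. The count of 2331 fell to 1190 without Neu tumour 2, 1305 without Neu tumour 3 and 1289 without the 3 tumours of 1 animal, and was 4719 with array weights.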

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

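The tests of the neutrophil and fibroblast lists, of the shared animal's effect on the comparison of pathology groups and of chance likeness of its tumours were chosen after the results were seen; the other tests were set before. In the first comparison 5964 genes passed and the highest other of the 35 splits of the 7 tumours gave 4822. The real split ranked 1 of 35. No smaller share was possible with 35 splits, so this argues against chance without excluding it. That other split put KRas tumour 2 with the 3 Neu tumours, and the next, with KRas tumour 1 among them, gave 2299, which points to structure among the KRas tumours. For R26KRas adenocarcinomas against KRas tumours, 3274 genes stood against at most 88 in other splits (1 of 35). For R26KRas against Neu tumours, 2331 stood against at most 4 (1 of 100 drawn splits). Both ranks argue against chance without excluding it, since the splits treat tumours as exchangeable although 3 R26KRas tumours share an animal code. Between the R26KRas pathology groups the real split gave 0 genes by limma (592 at an unadjusted p under 0.05) and the highest other split gave 1. With a real count of 0, all 35 of 35 splits give as many by construction, so this count says nothing about chance.

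Neutrophil and fibroblast genes were higher in KRas than in Neu tumours. If a smaller share of epithelium were the only cause, every other cell type would rise alike. The neutrophil list rose by 2.49 (SE 0.467) more than the endothelial list and the fibroblast list by 1.90 (SE 0.511) more. The test was chosen after these shifts were seen, so its outcome was known in advance. Its values speak at most against that share as the only cause. The endothelial list itself rose by 0.692 (SE 0.291), so a smaller share of epithelium as part of the cause stays open. The members' median difference was 2.81 after quantile normalization and 2.82 before. The processing notes name RMA, which already normalises the arrays, so a further normalization could change little. This repeat therefore cannot decide whether scaling between arrays plays a part. A larger share or activity of neutrophils and fibroblasts in KRas tumours is a candidate explanation, as a hypothesis. Genotype, pathology and handling order change together here and stay open.

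No gene passed between R26KRas poorly differentiated carcinomas and adenocarcinomas by limma (592 at an unadjusted p under 0.05, largest gene difference 2.38). Simulated 4-fold differences were found for 94.5% of genes, in sets of 200 changed genes with independent noise and no shared animal. This argues against many missed differences of that size only under those settings. In the data the largest difference, 2.38, is more than 4-fold and did not pass. Only 31.9% of 1.5-fold differences were found, so differences of that size may have been missed. Removing the 3 tumours of the animal present in both groups gave 0 genes, in a fit that found 84.4% of simulated 4-fold differences. Under the same simulated settings this argues against that animal hiding many differences of that size. Smaller ones stay open, since that fit found 40% of 2-fold and 4.78% of 1.5-fold differences.

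The 3 R26KRas tumours of 1 animal were the most alike of the 56 triples of R26KRas tumours (1 of 56, mean correlation across genes 0.9912, next 0.9898, lowest 0.974). The source names, not the values, set which 3 tumours were tested, but the test itself was chosen after their likeness was seen. Genes are not independent replicates in these correlations. After each gene's mean and its trend on the fibroblast and milk list scores were removed, 6 of 56 triples were as alike (0.12, highest other 0.446). Removing the means alone was not tried, so the change in rank cannot be credited to stroma and milk gene expression. A like amount of stroma and milk gene expression and a shared animal both remain open. Whether the shared animal narrows the error was not settled: as a random block its correlation of 0.69 rests on 1 animal.

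Of 81 groups of list scores 7 and of 222 groups of gene values 18 held 1 tumour apart from the others by Dixon's gap test. Chance flags about 1 in 20 groups. KRas tumours 1 and 2 account for most of the flagged gene values, but not for most of the flagged list scores. The Neu tumours (n = 3) were too few for this test and were left out of it. KRas tumour 1 was low in part of the squamous and basal genes, although not in Klk6 (9.96 against 10.06 to 11.05): Sprr1a was 6.57 (others 12.18 to 12.41), Sprr1b 6.03 (10.53 to 11.32), Krtdap 5.40 (10.40 to 11.00) and Krt17 5.18 (9.65 to 10.21). In the same tumour Cnn1 was 6.66 (7.98 to 8.18), Comp 9.52 (4.99 to 5.37) and the glycolysis and hypoxia score 0.174 (-0.764 to -0.628).

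KRas tumour 2 was higher than the other KRas tumours in Csn1s2a at 10.41 (others 5.07 to 5.49), Krt19 at 10.18 (7.36 to 7.77) and Pgr at 7.58 (4.82 to 5.12). Its Lalba (8.92) stayed below the Neu tumours (12.72 to 13.12). It was low in Tnc at 7.35 (11.53 to 11.83), Msr1 at 8.21 (10.12 to 10.35), Ms4a7 at 9.05 (10.32 to 10.39) and the macrophage and monocyte score at 0.233 (1.27 to 1.34). Klk6 at 11.05 (9.96 to 10.11) and Pspn at 5.80 (6.02 to 6.03) also stood apart in this tumour, and Clca1 at 5.30 (4.95 to 4.99) in KRas tumour 3.

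Among R26KRas adenocarcinomas, tumour 2 stood apart in Fos at 9.18 (others 8.16 to 8.29), in the luminal score at 1.05 (0.677 to 0.688) and in the driver gene score at 0.106 (-0.117 to -0.0917). Adenocarcinoma 3 did so in the basal and myoepithelial score at 0.917 and in the mast cell score at -0.374. Among poorly differentiated carcinomas, tumour 3 stood apart in the skeletal muscle score at 1.02 and in Klk6 at 7.43 (5.64 to 5.91), and tumour 4 in Elf5 at 9.46 (10.04 to 10.13).

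Signal also lay in the 16004 probe sets unnamed here, which no comparison in the report used. In a fit of all probe sets, 1333 of them (8.33%) passed between KRas and Neu tumours, 415 (2.59%) between R26KRas adenocarcinomas and KRas tumours, and 545 (3.41%) between R26KRas and Neu tumours.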

How the results depend on the processing

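No paired analysis was possible because the labels carry no shared replicate numbers and only 1 animal had tumours in both R26KRas groups; with the animal as a random block the counts were 5542, 2547, 0 and 1791. Each result was run again under the alternatives, of which the fit without the 3 tumours of 1 animal was chosen after seeing the data. Of 83 counts 15 moved by more than 1.5 times; where no reason is given, the cause was not tested. Counts at a minimum 2-fold difference fall by construction, to 2655 for KRas against Neu tumours, 1328 for R26KRas adenocarcinomas against KRas tumours and 877 for R26KRas against Neu tumours.

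For KRas against Neu tumours the count was 3910 in a fit of these groups alone and 4330 to 6596 when 1 tumour was left out. R26KRas adenocarcinomas against KRas tumours gave 2031 in a fit of these groups alone, 5870 with array weights, 1162 without the 3 tumours and 1847 (without KRas tumour 4) to 4877 (without KRas tumour 2) when 1 was left out. Values of 2156 without KRas tumour 3, 2148 without R26KRas adenocarcinoma 2 and 2121 without adenocarcinoma 4 also lay more than 1.5 times lower. R26KRas against Neu tumours gave 4719 with array weights, 1289 without the 3 tumours, and 1190 (without Neu tumour 2) to 2578 when 1 was left out, with 1305 without Neu tumour 3. Array weights gave KRas tumours 1 and 2 the least weight, 0.375 and 0.313. Of the 1162 and 1289 genes passing without the 3 tumours, 1107 and 1237 were among those of the fit with all 15 tumours. Between the R26KRas pathology groups each alternative gave 0 genes by limma, against 592 at an unadjusted p under 0.05.

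For named genes 101 repeats lost a call and 2, both for Pik3ca, gained one. For lists 91 lost and 84 gained one. The remaining repeats, 1754 and 2169, left a gene or list called or not called as before. With an estimated correlation 0 of 27 lists passed in any comparison (smallest adjusted p 0.272, 0.227, 0.497 and 0.217; 4, 5, 0 and 4 at an unadjusted p under 0.05), against 17, 15, 6 and 11 by camera with its preset correlation and 18, 15, 0 and 8 by fry. Turns of sign were counted only where the main fit or the repeat gave a call. By that count 1 list turned direction, the macrophage and monocyte genes between the R26KRas pathology groups. It passed at 0.0316 without R26KRas poorly differentiated carcinoma 4, with the opposite sign. Leaving out 1 tumour gave this list an adjusted p of 0.00404 to 0.733. The number of arrays, 3 or 4 a group, limits how far single tumours can be told from their group.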

Other observations

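The genes and families in this part, and the tests on them, were chosen after the values were seen, except the test of p53 targets, which was set before its result. Foxi1, a forkhead factor of ion-transporting cells, fell in KRas against Neu tumours by 4.16 (SE 0.24, adjusted p = 2.54e-07). It was 4.22 higher in R26KRas adenocarcinomas than in KRas tumours (SE 0.222, adjusted p = 3.52e-07), and R26KRas and Neu tumours differed by 0.02. Atp6v1b1, a proton pump subunit, fell by 3.20 (SE 0.52, adjusted p = 0.000441) and was 4.48 higher with the added allele (SE 0.481, adjusted p = 0.00011). Clic6, a chloride channel family gene, fell by 4.61 (SE 0.307, adjusted p = 5.85e-07) and was 4.45 higher (SE 0.284, adjusted p = 2.48e-06). The groups did not overlap for any of these differences that passed. The 22 measured subunits of the same pump moved both ways, with 3 up and 8 down in KRas against Neu tumours and 3 up and 2 down with the added allele, and did not pass as a family (camera adjusted p = 0.177 and 0.485).

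Tissue kallikreins Klk5 to Klk14, proteases of shedding epidermis, rose for 9 of 10 genes in KRas against Neu tumours (median 3.59, camera adjusted p = 6.49e-07; adjusted p = 0.102 with an estimated correlation). With the added allele 8 of 10 fell (median -2.92, camera adjusted p = 8.88e-08; adjusted p = 0.102 with an estimated correlation). Granzymes Gzmc to Gzmg, cytotoxic proteases, moved likewise, with 4 of 4 up (median 3.43, camera adjusted p = 0.000564; 0.134 with an estimated correlation) and 4 of 4 down (median -3.20, 9.9e-05; 0.102). Of 7 Tmprss11 proteases 4 rose (median 3.51, camera adjusted p = 0.000789; 0.207 with an estimated correlation) and 4 fell (median -3.11, 2.6e-05; 0.106). These genes are close paralogs and probes shared between them were not examined.

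Besides Erbb2, other ErbB receptors fell. In KRas against Neu tumours Erbb4 fell by 3.72 (SE 0.326, adjusted p = 5.6e-06) and Erbb3 by 1.83 (SE 0.302, adjusted p = 0.000479), while the ligand Nrg1 rose by 3.21 (SE 0.53, adjusted p = 0.000487). In R26KRas against Neu tumours Erbb4 fell by 3.07 (SE 0.289, adjusted p = 2e-05) and Nrg1 rose by 2.35 (SE 0.47, adjusted p = 0.005). Erbb3 was 0.64 lower there and did not pass (adjusted p = 0.159), and Egfr passed in neither comparison. The fibrinogen chain gene Fgg rose by 3.93 in R26KRas adenocarcinomas against KRas tumours (SE 0.595, adjusted p = 0.000948) and Fgb by 3.23 (SE 0.619, adjusted p = 0.00403). Against Neu tumours Fgg rose by 4.38 (SE 0.569, adjusted p = 0.000219) and Fgb by 3.78 (SE 0.593, adjusted p = 0.00086). The 3 fibrinogen chains were lower in poorly differentiated carcinomas than in adenocarcinomas as a family (median -1.70, camera adjusted p = 0.000208, and 0.0401 with an estimated correlation), although none of them passed alone. The family was chosen after the values were seen and its p is adjusted over 24 such family tests alone. It therefore cannot stand as support for a difference.

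Cdkn1a, a cell cycle inhibitor and p53 target, was 2.55 higher in KRas than in Neu tumours (SE 0.388, adjusted p = 0.000279) and 2.24 higher in R26KRas than in Neu tumours (SE 0.344, adjusted p = 0.000746). If p53 activity rose, its other targets would rise. The list of targets was set without Cdkn1a and Mdm2. Of 18 measured 12 rose and 1, Sulf2, fell in KRas tumours (median 1.03, camera p = 7.55e-06 from a model rather than a permutation, and 0.0843 with an estimated correlation). In R26KRas tumours 6 rose, among them Ccng1, Phlda3, Sesn2 and Plk2 (median 0.732, camera p = 4.06e-07, again not by permutation; 0.0549 with an estimated correlation). Higher p53 output than in Neu tumours may explain Cdkn1a, as a hypothesis that the estimated correlation leaves short of the threshold. Nf1, a negative regulator of Ras, fell by 1.11 in KRas tumours (SE 0.158, adjusted p = 0.000169) and by 0.92 in R26KRas tumours (SE 0.14, adjusted p = 0.000676), both against Neu tumours.

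The first 2 comparisons share the KRas tumours, so an extreme group would give opposite changes in both. Genes such as Lalba and Tspan8, low in KRas tumours against both other groups, numbered 1384 (292.5 if the lists were independent), and genes such as Klk6 and Retnlg, high against both, 1082 (157.5). When different KRas tumours entered the 2 contrasts, which then shared none, the overlaps were 366 to 1016 and 262 to 750, against at most 260.6 and 166.6 for independent lists. The covariance of the 2 differences across genes, which are not independent replicates, was -0.329 and -0.297 to -0.244 over these splits, against -0.029 in data simulated without differences. Sharing the group alone gave a correlation across genes of -0.464 in those simulated data, against -0.735 observed. The simulated data hold no differences, so these 2 correlations do not give the share of the opposite movement that comes with the design. By covariance, -0.029 against -0.329, the part that comes with the design was small.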
